A study of Solanum lycopersicum with 10 samples.

How the data were processed

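The series measured polyadenylated transcripts in tomato (Solanum lycopersicum), line M82, with a 3' end sequencing kit that yields 1 fragment per transcript. It holds 10 libraries in 4 groups: root tips under mock treatment (n = 2), root tips on 2,4-D (n = 2), leaf primordia under mock treatment (n = 3) and leaf primordia sprayed with picloram (n = 3). Groups and replicate numbers came from the sample titles, and each column of the table matched the title of 1 sample.

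The deposited table lists 35767 loci by Solyc identifier for the 10 libraries. The values are a non-negative signal, gene counts that the authors had already normalized: Salmon 0.8.2 and DESeq2 are named, without roles, in the submitters' processing notes. The genome build and annotation are not given in the sources used here. Low values in each library lay near whole multiples of 1 step, which was worth 0.785 to 1.22 normalized counts, but the step varied by locus (5th to 95th percentile 0.933 to 1.06 of the library step at the extremes of the libraries). With a tolerance of 0.1 read and a reach of 20 reads, 57.6% to 82.6% of low values per library came out whole, so whole reads could not be recovered and no test on read counts was run. The test for counts written before the data were examined was therefore replaced by the test named there for normalized values.

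That test was the moderated linear model of limma 3.58.1 with a mean-variance trend (R 4.3.3), on log2(value + 1), with 1 mean per group over all 10 libraries, so that the root groups of 2 shared the estimate of the spread. Residual degrees of freedom were 6 and the prior added 5.55. Fold changes are on the log2(value + 1) scale, which understates the change of low loci. A locus was called at a Benjamini-Hochberg adjusted p under 0.05, 2-sided. The contrasts were 2,4-D against mock in root, picloram against mock in leaf, the root response minus the leaf response, and mock root against mock leaf.

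A locus was tested in a tissue where at least 10 was reached in at least 2 libraries of that tissue, in both tissues for the difference of responses, and in either tissue for the tissue comparison. Treated libraries count too, so a locus low in mock enters mostly where it rose, and one low under treatment mostly where it fell. Where a library was left out, the minimum was applied to the libraries that remained. This minimum was not fixed beforehand. A first version, at least 10 in at least 2 of all 10 libraries, had already been run on the data and had called 650 loci in root, 1421 in leaf and 636 for the difference. Simulated data then showed that 21.2% of its root calls and 5.41% of its leaf calls were false, and the minimum was set per tissue in its place. With the minimum per tissue, 1.82% of simulated root calls and 0.709% of leaf calls were false. In the simulation of 12360 root loci, 100 were changed by each fold, and 16% of 2-fold and 92% of 4-fold changes were recovered. In that of 14080 leaf loci, 41% and 99% were recovered. Changed loci had mock means well above the minimum of 10, so recovery nearer the minimum can be lower. Fewer loci were changed than were called in the data, which makes the adjusted threshold stricter. The simulation drew negative binomial counts with a dispersion of 0.03, and real loci can vary more.

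The table carries no gene names, and the RefSeq gene table used here (SLM_r2.1, 41476 rows) names 0 Solyc identifiers, so the files do not pair identifiers with names. Of 31 gene lists fixed before the data were examined, 10 held identifiers recalled from the literature on each family and were used. The other 21 were patterns on gene descriptions and could not be tested. Membership was not checked gene by gene. For 4 lists, a RefSeq symbol of the family lay on the chromosome in the identifier for 16 of 21 Aux/IAA loci, 7 of 8 GH3 loci, 18 of 18 ARF loci and 12 of 12 auxin transport loci. A list of 15 light-harvesting and Rubisco small-subunit loci and lists of morning-phased and evening-phased clock loci were added after the data had been examined, the clock lists after the value of 1 clock locus had been seen. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives.

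Loci were named by a rule fixed beforehand: for each auxin comparison the 8 with the highest and the 8 with the lowest fold change among called loci with no overlap between treated and mock libraries, up to 3 called members per list or else the member of highest level, the 5 highest and lowest for the difference and the tissue comparison, and the 8 shared loci of smallest adjusted p. Because names are lacking, at most 2 loci that rose and 2 that fell are printed per comparison from outside the lists, apart from loci raised in the closing part. Overlaps were tested with Fisher's exact test, 2-sided.

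Library totals were 2.83 to 2.96 M normalized counts in root and 1.83 to 2.06 M in leaf. Division by the step gives about 2.32 to 3.47 M reads in root and 1.69 to 2.39 M in leaf, so values near 1 rest on about 1 read. No 2 libraries held identical values, and replicates differed by more than counting noise (chi-square per locus 2.17 to 6.67). The labels do not say that replicates came from separate plants, so p-values measure the spread between these samples, which may be technical. Alternatives covered the pseudocount, the minimum, each tissue fitted alone, a replicate block, stricter thresholds, other scalings, robust moderation and leaving out libraries.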

Results

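The transcript response to synthetic auxin was measured in 2 tomato experiments. In the first, seedlings of line M82 raised on plates at 22 °C in continuous light were moved 4 days after germination to medium with 1 µM 2,4-D, a stable auxin analog, and the terminal 1 cm of the root was taken after 3 h. In the second, greenhouse plants aged 3 weeks were sprayed with 1 µM picloram, another auxin analog, and 15 primordia of leaf 5 were collected after 3 h. Each arm had its own mock control, with 2 libraries per root group and 3 per leaf group. Totals were 2.83 to 2.96 M normalized counts per root library and 1.83 to 2.06 M per leaf library. Root and leaf libraries, which differ in plant age, growth conditions and treatment as well as tissue, stood apart on the first principal component, with 81.6% of the variance.

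Which transcripts respond to auxin in the root tip was asked by comparing 2,4-D with mock. In the Aux/IAA list, whose products are repressors of auxin signalling and are classic early auxin targets, 6 of 15 tested members rose and 0 fell. The other 9 were not called, and 4 of the 15 fold changes were below 0. Among the 6, Solyc06g084070 and Solyc03g120390 reached the minimum only with the 2,4-D libraries, an entry that favours a rise. Solyc06g084070 went from 3.20 ± 0.0548 to 29.4 ± 0.695 normalized counts (SD, n = 2), a log2 fold change of 2.85 ± 0.40 (SE, adjusted p = 0.00153). Solyc04g076850, at far higher levels, rose from 1039 ± 13.7 to 2027 ± 151 (SD, n = 2), or 0.96 ± 0.15 on the log2 scale (SE, adjusted p = 0.0027), and Solyc03g120500 rose by 1.60 ± 0.25 (SE, adjusted p = 0.00326). The call of Solyc04g076850 ended without 2,4-D library 1, and that of Solyc03g120500 without 2,4-D library 2. Without 2,4-D library 1 or 2 the list had 1 of 12 tested members that rose, and without mock library 1 or 2 it had 3 or 4 of 15. Where a 2,4-D library was left out, Solyc06g084070 and Solyc03g120390 no longer reached the minimum. They were not tested there, although both were called with all 10 libraries. With all 10 libraries and adjusted over the list alone, 8 Aux/IAA members rose and 1 fell. The list had a median log2 fold change of 0.96 and was higher than other loci by camera (adjusted p = 6.12e-05, and adjusted p = 0.0171 with an estimated correlation).

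Of the GH3 list, enzymes that conjugate auxin to amino acids, 1 of 2 tested members rose in root: Solyc01g107390, from 9.40 ± 2.44 to 46.4 ± 13.8 normalized counts (SD, n = 2), by 2.18 ± 0.46 (SE, adjusted p = 0.0201). Of the auxin transport list 1 of 10 rose, Solyc10g080880, by 1.18 ± 0.24 (SE, adjusted p = 0.017). Both calls ended when any 1 of the 4 root libraries was left out and after quantile normalization (adjusted p up to 0.231 for Solyc01g107390 and 0.591 for Solyc10g080880 over all alternatives). The other GH3 member, Solyc02g092820 (1.20 ± 0.31, SE, adjusted p = 0.0524), was not called. It passed with the replicate block (adjusted p = 0.0227), recomputed median ratios, equal library totals or robust moderation. It also passed without mock leaf library 3 or picloram library 1 or 3. All 3 tested loci of the ethylene biosynthesis list, enzymes that make and oxidize aminocyclopropane carboxylate, were called in mixed directions. Solyc02g081190 rose by 2.15 ± 0.36 (SE, adjusted p = 0.00456) and Solyc12g005940 by 1.19 ± 0.30 (SE, adjusted p = 0.0441), while Solyc03g043890 fell by 3.11 ± 0.45 (SE, adjusted p = 0.00206). The fall came from low levels near the minimum, 11.7 and 12.2 normalized counts in mock against 0 and 1.25 on 2,4-D. The call of Solyc02g081190 ended without mock library 1 or 2,4-D library 2 (adjusted p up to 0.182 over the alternatives). That of Solyc12g005940 ended in 12 of 22 alternatives, each omission of 1 root library among them (adjusted p up to 0.678). The 1 tested locus of the gibberellin metabolism list, Solyc01g079200, stood at 0 and 1.09 normalized counts in mock and at 30.6 and 24.6 on 2,4-D, a log2 fold change of 4.30 ± 0.54 (SE, adjusted p = 0.000838). It too reached the minimum only with the 2,4-D libraries. Of the ARF list, the transcription factors that Aux/IAA proteins repress, 0 of 10 were called by limma, and Solyc01g096070 had a log2 fold change of 0.36 ± 0.25 (SE, adjusted p = 0.539). None of 3 receptor loci was called, with Solyc09g074520 at -0.01 ± 0.20 (SE, adjusted p = 0.991). Nor was the 1 tested locus of the auxin biosynthesis list, Solyc09g091090 (1.16 ± 0.59, SE, adjusted p = 0.368), or of the KNOX and BELL homeobox list, Solyc05g005090 (-0.17 ± 0.57, SE, adjusted p = 0.932). Adjusted over the list alone, GH3 had 2 members that rose, ARF 1 and transport 1, ethylene biosynthesis had 2 that rose and 1 that fell, gibberellin metabolism had 1 that rose, and the receptor, auxin biosynthesis and homeobox lists had 0. No tested locus came from the TCP list.

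In all, 576 of 12664 loci were called in root, of which 441 rose and 135 fell, and 2066 had an unadjusted p under 0.05. The locus with the highest rise was Solyc00g072400, at 0 and 1.12 normalized counts in mock against 342 and 222 on 2,4-D, but Solyc10g076243 had equal values in all 10 libraries, so the count of either is uncertain. Solyc01g079390 fell from 132 ± 71.3 to 0.535 ± 0.269 (SD, n = 2) and Solyc08g076335 from 74.2 ± 57.9 to 1.22 ± 1.73 (SD, n = 2). The call of Solyc01g079390 ended without 2,4-D library 1 or 2 (adjusted p up to 0.122). The number of root calls rested on each library: it was 90 or 100 without 2,4-D library 1 or 2, 248 (239 that rose, 9 that fell) or 351 (322 and 29) without mock library 1 or 2, and 55 without both libraries numbered 2, where 1 Aux/IAA locus rose. It was 1141 (728 and 413) with root fitted alone and 327 after quantile normalization, with 3 Aux/IAA loci rising. Part of the drop without a root library follows from the minimum, applied to the libraries that remained. Where a 2,4-D library was left out, loci under 10 in both mock libraries, such as Solyc00g072400, were not tested. Where a mock library was left out, the same held for loci under 10 in both 2,4-D libraries, such as Solyc01g079390.

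**Figure D1:**
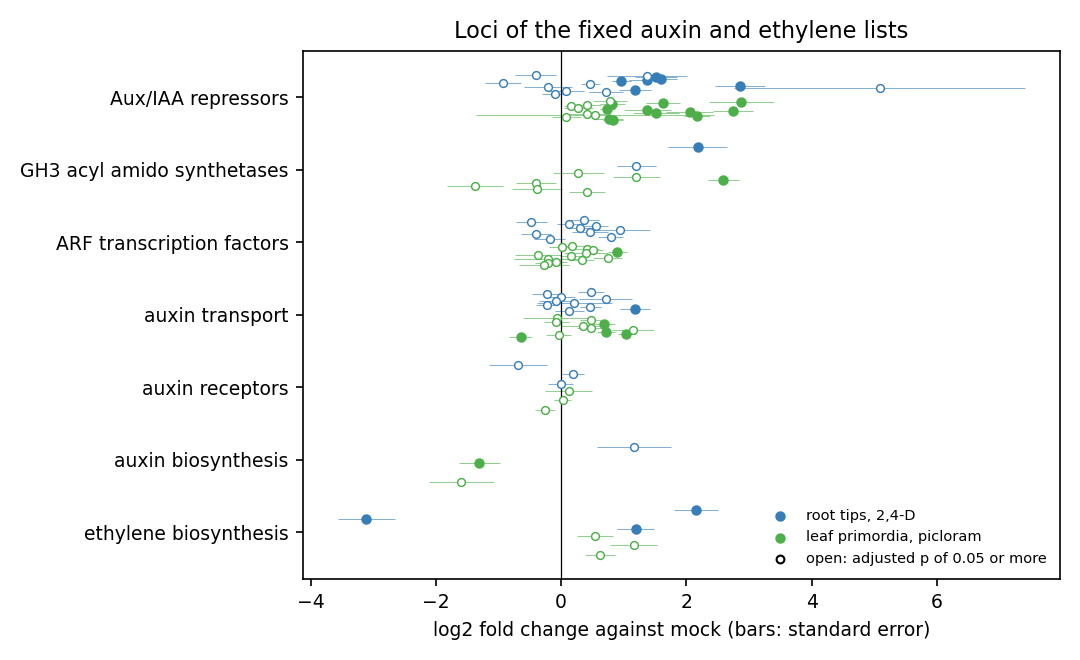
Log2 fold change against mock (x axis) of each tested locus of 7 fixed lists (y axis), in root tips on 2,4-D (blue) and leaf primordia under picloram (green), with standard errors as bars. Filled points passed an adjusted p of 0.05, among them 6 Aux/IAA loci in root and 11 in leaf, all above 0.

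The same question was put to leaf primordia by comparing picloram with mock. Aux/IAA loci again rose, 11 of 18 tested members, and 0 fell. Of these, Solyc06g084070, Solyc03g120380, Solyc08g021820 and Solyc06g066020 reached the minimum only with the picloram libraries, an entry that favours a rise. Solyc09g083280 went from 33.3 ± 10.2 to 149 ± 9.96 normalized counts (SD, n = 3), a log2 fold change of 2.17 ± 0.21 (SE, adjusted p = 0.000115), Solyc06g084070 from 3.91 ± 1.04 to 32.3 ± 8.89 (SD, n = 3), by 2.75 ± 0.32 (SE, adjusted p = 0.000413), and Solyc03g120390 rose by 1.63 ± 0.27 (SE, adjusted p = 0.00345). Without mock library 2 or any 1 picloram library, 7 of 18 rose. Adjusted over the list alone, 12 rose and 0 fell. The median of the list was 0.80 on the log2 scale (camera adjusted p = 1.5e-09, and adjusted p = 0.00286 with an estimated correlation).

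Of the GH3 list 1 of 7 rose, Solyc02g092820, from 95.6 ± 20.1 to 599 ± 213 normalized counts (SD, n = 3), by 2.59 ± 0.25 (SE, adjusted p = 0.000134). In the auxin transport list, made up of efflux and influx carriers, 3 of 11 rose and 1 fell. Solyc10g078370 rose by 1.04 ± 0.14 (SE, adjusted p = 0.000924), Solyc09g014380 by 0.72 ± 0.14 (SE, adjusted p = 0.00797) and Solyc03g118740 by 0.69 ± 0.18 (SE, adjusted p = 0.0314), and Solyc11g013310 fell by 0.65 ± 0.18 (SE, adjusted p = 0.0477; named after its value was seen). The fall of Solyc11g013310 lost its call in 18 of 22 alternatives, each omission of 1 library among them (adjusted p up to 0.146). The rise of Solyc03g118740 lost its call without mock library 2 or 3 or picloram library 1 or 3 (up to 0.111). The transport list passed camera (adjusted p = 0.0235) but not with an estimated correlation (adjusted p = 0.256). In the ARF list 1 of 14 rose, Solyc05g047460, by 0.90 ± 0.15 (SE, adjusted p = 0.00365). In the auxin biosynthesis list 1 of 2 fell, Solyc06g065630, by 1.30 ± 0.32 (SE, adjusted p = 0.0261). That call ended with the replicate block, without mock library 3, picloram library 2 or picloram library 3, and with no minimum on low values (adjusted p up to 0.0895 over the alternatives). No call was made among 3 receptor loci (Solyc09g074520, -0.26 ± 0.16, SE, adjusted p = 0.357), 3 ethylene biosynthesis loci (Solyc02g081190, 0.54 ± 0.29, SE, adjusted p = 0.278), 1 gibberellin locus (Solyc03g006880, -1.20 ± 0.48, SE, adjusted p = 0.139) or 1 homeobox locus (Solyc05g005090, 1.01 ± 0.46, SE, adjusted p = 0.203). Adjusted over the list alone, GH3 had 2 that rose and 1 that fell, transport 5 and 1, ARF 3 and 0, ethylene biosynthesis 2 and 0, auxin biosynthesis 0 and 2, gibberellin metabolism 0 and 1, and the receptors and homeobox loci 0 and 0.

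Across all tested loci, 1463 of 14410 were called in leaf, 705 that rose and 758 that fell, with 3593 at an unadjusted p under 0.05. Solyc05g015800 went from 1.01 ± 1.10 to 74.7 ± 17.5 normalized counts and Solyc07g061730 from 2.09 ± 1.16 to 60.4 ± 6.64, while Solyc02g078450 fell from 114 ± 19.6 to 2.18 ± 3.77 and Solyc04g014770 from 87.2 ± 27.7 to 2.33 ± 2.44 (SD, n = 3 each). Of 7 tested loci on clock lists, which were added after 1 clock locus had been seen among the leaf results, 4 were called in leaf: morning-phased Solyc10g005080 rose by 3.06 ± 0.15 (SE, adjusted p = 2.06e-06), and evening-phased Solyc12g056650 fell by 1.77 ± 0.16 (SE, adjusted p = 6.84e-05), as did 2 other evening-phased loci. The list of both phases was not called by camera (adjusted p = 0.246), and the evening-phased list was lower (adjusted p = 0.00229, and adjusted p = 0.0535 with an estimated correlation). With equal library totals 61.5% of leaf calls rose (888 against 555), in place of 48.2%. The count was 972 without mock library 2, 962, 876 and 949 without picloram libraries 1, 2 and 3, and 919 without both root libraries numbered 2, which enter the shared estimate of the spread.

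**Figure D2:**
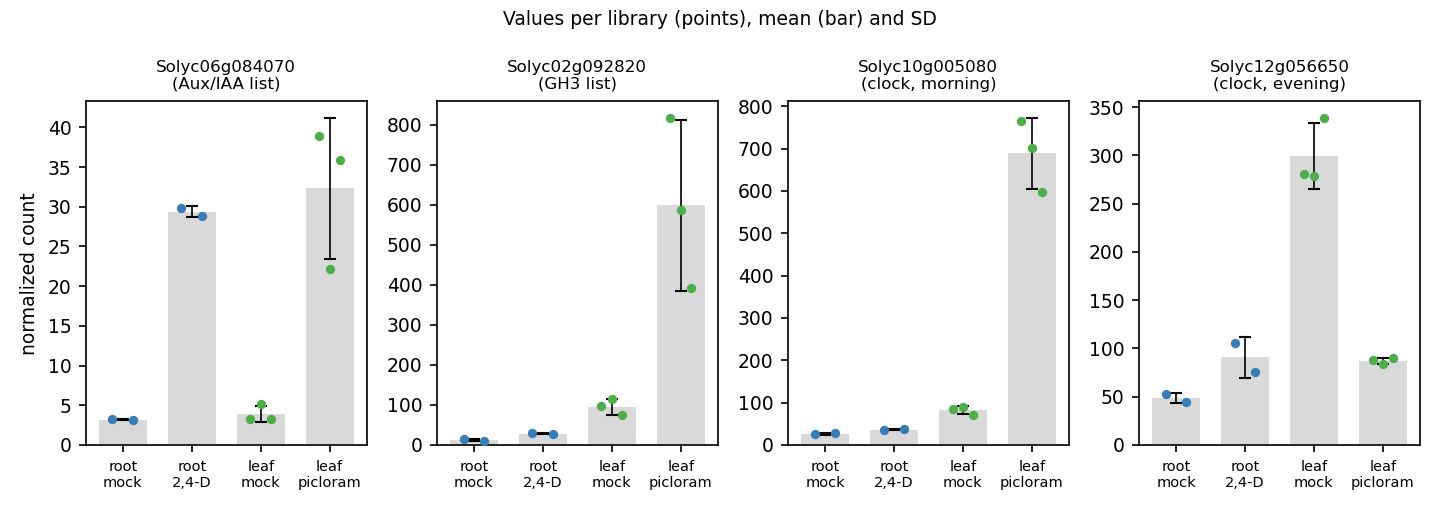
Normalized counts (y axis, linear from 0) of 4 loci in the 4 groups (x axis), with each library as a point, the group mean as a bar and the SD as an error bar. Solyc06g084070 stood at 3.20 in mock root and 29.4 on 2,4-D, and Solyc10g005080 rose in leaf under picloram.

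Whether both experiments moved the same loci was examined over 11313 loci tested in both. In root and leaf alike 65 loci rose, against 13.8 for independent lists (Fisher's exact test, adjusted p = 4.67e-26), and 27 fell, against 6.92 (adjusted p = 1.28e-09). Besides the Aux/IAA locus Solyc06g084070, they included Solyc09g007765, which rose by 1.62 ± 0.18 in root and by 2.66 ± 0.14 in leaf, where its response was the larger (SE, adjusted p = 0.000344 and 2.97e-06, and 0.0284 for the difference, lost without any 1 root library or picloram library 1 or 2, with adjusted p up to 0.482), and Solyc08g077780, which rose by 1.98 ± 0.20 and 1.30 ± 0.16 (SE, adjusted p = 0.000201 and 0.000551). Opposite calls also occurred: 23 loci fell in root and rose in leaf, against 5.23 (adjusted p = 2.08e-09), and 14 rose in root and fell in leaf, against 18.3 (adjusted p = 0.39). The 23 became 2, 8, 3 and 7 without root mock 1, root mock 2, 2,4-D 1 and 2,4-D 2, and 14 without picloram 2 or 3. The 27 that fell in both became 2, 7, 3 and 3 without those root libraries, 13 without picloram 1 or 2, 17 without picloram 3 and 48 without mock leaf 1. With equal library totals 15 loci fell in both, after quantile normalization 7 and with no minimum on low values 13, against 4.21, 2.76 and 2.75 expected. Across loci, which are not independent replicates, the 2 responses correlated weakly over all tested loci (r = 0.121, rho = 0.125). The correlation was higher among the 129 loci called in both (r = 0.341, rho = 0.356), but selecting loci that changed in both can by itself raise it. The 92 loci called in the same direction became 157 with each tissue fitted alone, 50 after quantile normalization and 8 without both root libraries numbered 2. They became 34, 50, 15 and 16 without root mock 1, root mock 2, 2,4-D 1 and 2,4-D 2, and 58, 51 and 60 without picloram 1, 2 and 3. Part of each drop without a root library can follow from the minimum, applied to the libraries that remained. An estimate of the spread enters both tests. With each tissue fitted alone, which leaves it unshared, 91 loci rose in both against 22.3 expected, 66 fell in both against 16.6, and 33 fell in root and rose in leaf against 15.3.

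**Figure D3:**
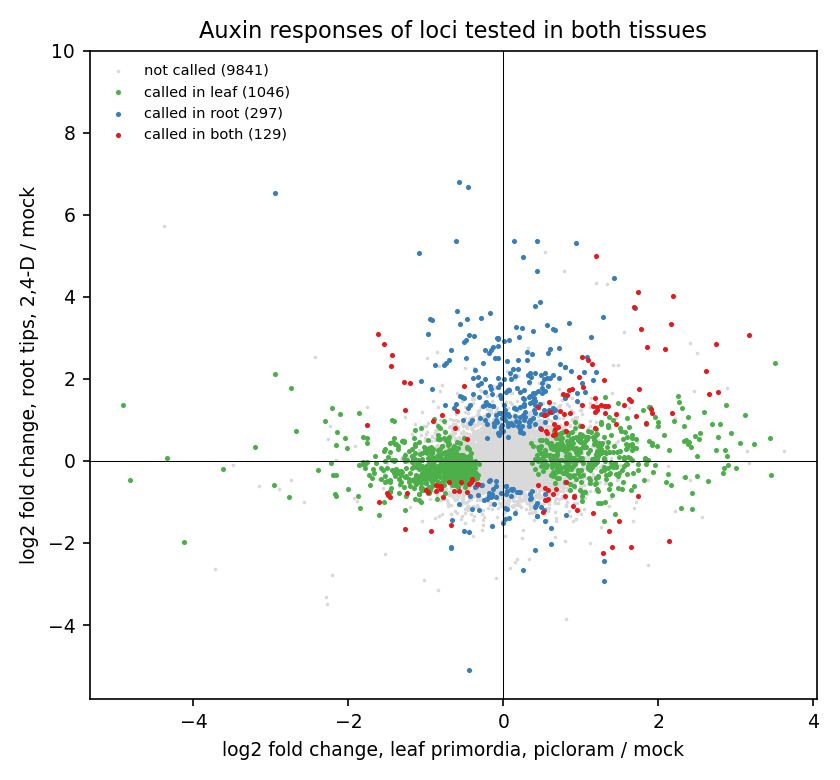
Log2 fold change under 2,4-D in root tips (y axis) against that under picloram in leaf primordia (x axis) for 11313 loci tested in both, coloured by where they were called. The 129 loci called in both lie mostly in the quadrants of equal sign, 92 against 37.

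The difference of the responses was tested directly. It compares the experiments as wholes, since tissue, compound, plant age, growth conditions and application changed together. The Aux/IAA list as a whole was not called (camera adjusted p = 0.549). Within it Solyc04g076850 responded more in root, by 0.80 ± 0.19 (SE, adjusted p = 0.0387), and Solyc06g084070 was not called (0.11 ± 0.51, SE, adjusted p = 0.943). The carrier locus Solyc09g014380 had a response lower in root by -0.95 ± 0.22 (SE, adjusted p = 0.0391). Both calls ended when any 1 root or picloram library was left out (adjusted p up to 0.357 and 0.324 over the alternatives). Adjusted over the list alone, Aux/IAA had 1 member with the higher response in root and 3 in leaf, and 10 of 15 differences were below 0. Transport had 1 and 1, GH3 0 and 1, and ethylene biosynthesis 1 and 0. The transport list (adjusted p = 0.549), the ARF list (adjusted p = 0.549) and the receptors (adjusted p = 0.971) were not called by camera. In total 425 of 11313 loci differed, 249 with the higher response in root and 176 in leaf. Of 297 loci called in root and not in leaf, 141 passed this test, as did 212 of 1046 called in leaf and not in root. Where a 2,4-D library was left out, loci under 10 in both mock root libraries were not tested. This takes loci that rose in root from low levels out of the count of loci that differed, and so favours leaf. The count was 197, 217, 167 and 174 without root mock 1, root mock 2, 2,4-D 1 and 2,4-D 2, the last 2 with more loci higher in leaf (87 against 80 and 95 against 79), and 25 without both root libraries numbered 2.

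Mock root tips and mock leaf primordia were compared as a baseline. The GH3 list was lower in root, with 6 of 7 tested members called lower and a median log2 difference of -4.25 (camera adjusted p = 0.00431, and adjusted p = 0.0869 with an estimated correlation). Of these, 2 reached the minimum in root and 7 in leaf, so most entered through leaf, which favours a lower value in root. Over all 15761 loci, 4695 were called lower in root. Of the ARF list 9 of 15 were lower in root and 2 higher (camera adjusted p = 0.0127, and adjusted p = 0.469 with an estimated correlation). Aux/IAA loci were divided, 5 higher and 6 lower of 18, as were transport loci, 5 and 6 of 12, and neither list was called by camera (adjusted p = 0.912 for both), although Aux/IAA passed fry as lower in root (adjusted p = 0.000414). All 15 light-harvesting and Rubisco small-subunit loci, a list added after the data were examined, were lower in root, by a median of -7.85 (camera adjusted p = 1.12e-10, and adjusted p = 0.0835 with an estimated correlation). Only 1 of them reached the minimum in root, so this direction too was favoured by the way the loci entered. Leaf-abundant loci were selected by a high mean in leaf and a root mean that was a small part of it, so low root shares follow from the choice. For these loci, root libraries held 0.276% and 0.333% of the leaf level in mock 1 and 2,4-D 1, and 0.771% and 1.19% in mock 2 and 2,4-D 2.

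Of 15761 loci, 9855 differed between the mock tissues, 5160 higher in root and 4695 higher in leaf. Solyc04g009590 averaged 7508 ± 561 normalized counts in root (SD, n = 2) and 4.06 ± 7.03 in leaf (SD, n = 3), and Solyc08g074680 averaged 3445 ± 1158 and 3.58 ± 4.37. Solyc09g084480 and Solyc11g006250 were listed at 0 in both mock root libraries and stood at 1210, 1320 and 1246 and at 1302, 1274 and 1050 in the mock leaf libraries. With equal library totals, which moved the median of all loci to -0.45, 32.2% of the calls were higher in root (3187 against 6713), in place of 52.4%.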

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

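The tests on clock loci, library scaling included, and that on single library pairs were chosen after the results had been seen, and the correction for measurement error before.

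Among the loci named in the text, 11 passed the test of the difference between the root response and the leaf response. Solyc08g062950, Solyc11g010280, Solyc08g076335 and Solyc09g010430 were named because they passed it, so their passing is no separate support. Neither tissue response was called for Solyc08g062950 (adjusted p = 0.0786 in root and 0.0615 in leaf) or Solyc09g010430 (0.127 and 0.105). Solyc08g062950 differed by 10.1 ± 2.12 (SE, adjusted p = 0.0222) and Solyc11g010280 by 9.47 ± 2.15 (SE, adjusted p = 0.0321). The first was listed at 0 in both mock root and all picloram libraries, at 78.3 and 34.2 on 2,4-D, and at 0, 97.0 and 90.1 in mock leaf. The second was listed at 0 in both mock root libraries and in picloram library 1, and at 85.2 and 119 in picloram libraries 2 and 3. Both calls ended with robust moderation and without mock root library 1 or 2, the first also without any 1 picloram library, and the second without mock leaf library 2 and after quantile normalization. Solyc08g076335 differed by -4.65 ± 0.875 (SE, adjusted p = 0.0123), a call that ended without 2,4-D library 1. Solyc09g010430 differed by -4.39 ± 1.06 (SE, adjusted p = 0.0426). The call of Solyc09g010430 ended without either 2,4-D library, mock leaf library 2 or picloram library 1. It also ended with a pseudocount of 0.5, no minimum on low values, equal library totals or quantile normalization. Solyc04g014770 differed by 6.26 ± 0.737 (SE, adjusted p = 0.000743), and Solyc09g007765, which rose in both tissues, by -1.03 ± 0.227 (SE, adjusted p = 0.0284), a call that ended without any 1 root library or picloram library 1 or 2 (adjusted p up to 0.482 over the alternatives). The Aux/IAA locus Solyc04g076850 differed by 0.80 ± 0.19 (SE, adjusted p = 0.0387) and the carrier locus Solyc09g014380 by -0.946 ± 0.223 (SE, adjusted p = 0.0391).

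The other 3 were clock loci. Solyc10g005080 differed by -2.61 ± 0.23 (SE, adjusted p = 0.000144), Solyc12g056650 by 2.64 ± 0.25 (SE, adjusted p = 0.000202) and Solyc04g071990 by 2.56 ± 0.56 (SE, adjusted p = 0.028). In leaf, morning-phased Solyc10g005080 rose by 3.06 and evening-phased Solyc04g071990, Solyc12g056650 and Solyc03g081240 fell, with log2 fold changes of -2.16, -1.77 and -2.72. Morning-phased Solyc10g005030 (0.16) and evening-phased Solyc08g065870 (-0.04) and Solyc01g068160 (0.90) were not called. The last had a sign opposite to that of the called evening-phased loci. In root, Solyc12g056650 rose by 0.87 (adjusted p = 0.0231), a call lost without mock library 1 or 2 or 2,4-D library 1. The difference of Solyc04g071990 lost its call without any 1 root library or mock leaf library 2 (adjusted p up to 0.456 over the alternatives).

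The tables argue against library scaling as the origin of this clock pattern. A factor per library moves every locus alike, whereas the called clock loci went both ways by at least 1.77 log2 units, and 3 rescalings moved the median leaf locus by at most 0.0842. A candidate explanation is that mock and picloram leaves were taken at different times of day, but the labels record no time of sampling. Of 7 tested clock loci the 4 called all moved as their phase would have it, and those of the 4 tested in root, in continuous light, moved by at most 0.873. The uncalled loci do not add to this pattern. An effect of picloram on the clock predicts the same 4 movements, so the 2 explanations cannot be told apart from these values.

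The weak correlation of root and leaf responses was weighed against measurement error. The mean correlation of single root pairs with single leaf pairs was 0.0848. Divided by the square root of the product of the agreement of separate pairs within root (0.55) and leaf (0.402), it came to 0.18 (95% bootstrap interval over loci 0.132 to 0.233). This lies below the bound of 0.5 set beforehand, so measurement error alone, gauged in this way, does not account for it. The interval holds the libraries fixed, and the agreement within root is a single correlation. A difference shared by all pairs of a tissue counts as agreement. Tissue, auxin analog, plant age, growth conditions and mode of application changed together and cannot be told apart. A difference in time of day between mock and picloram leaves, for which the labels hold no record, would also enter the leaf response. It would thereby enter the other leaf calls and the difference of responses.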

How the results depend on the processing

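The scalings, robust moderation, the minimum over all 10 libraries and the omission of both root libraries numbered 2 were chosen after seeing the data. Planned fits that need read counts (other size factors, other count tests, rounding, their robust form) were not run. In the simulation, a 2-fold change in root was recovered in 16% of 100 changed loci, all with mock means well above the minimum. This limits negative statements there.

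With each tissue fitted alone, root calls were 1141 and shared calls 157. A 2-fold minimum left 750 leaf calls. An adjusted p under 0.01 left 271 root, 613 leaf and 170 difference calls. Quantile normalization gave 327 root and 50 shared calls. Without both root libraries numbered 2, where 1 root library stands per group and is assumed to vary like the others, 55 root, 919 leaf, 25 difference and 8 shared calls were left. Leaving out 1 library at a time gave 90 to 669 root, 876 to 1594 leaf, 167 to 473 difference, 8113 to 9773 tissue and 15 to 122 shared calls. Fewer samples enter those fits, and the minimum, applied to the libraries that remained, leaves out loci low in the other group of the tissue. The cause of the other movements was not tested. All other alternatives kept these total counts within 1.5 times, while some counts by direction moved more.

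Replicate numbers were not taken to pair the samples: deviations of equally numbered libraries correlated at 0.108 in root and at 0.0725, -0.0266 and -0.0266 in leaf. The root value is a single one, since with 2 libraries per group the deviations mirror each other. In root, 74 of 163 leaf-abundant loci were higher in both libraries numbered 2 and 4 in both numbered 1. A difference shared by number is thus not excluded there. The replicate block gave 519 root, 1391 leaf, 414 difference and 84 shared calls, 9 light-harvesting and Rubisco loci called in leaf in place of 4, an adjusted p of 0.0398 for ethylene biosynthesis in leaf, and no call of Solyc06g065630 or Solyc11g013310 there.

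With fry the ethylene biosynthesis and GH3 lists passed in leaf (adjusted p = 0.0379 for both) and, between mock tissues, ethylene biosynthesis (higher in root, adjusted p = 0.0104), auxin biosynthesis and Aux/IAA (lower in root, adjusted p = 0.000414 for both), and with an estimated correlation auxin transport in leaf did not (adjusted p = 0.256). The Aux/IAA list kept its call in both tissues with all list alternatives. Of 64 pairs of a named locus and a comparison, 53 were called. Of these 31 kept the call under every alternative that tested them and 22 lost it under at least 1, none with a change of sign: 124 of 1100 values no longer passed. In root, 19 of 22 alternatives tested Solyc06g084070 and 18 of 22 tested Solyc00g072400, Solyc10g076243, Solyc01g079200 and Solyc03g043890. The minimum kept these loci out where a library that held their signal was left out, so they met fewer strict alternatives than other loci. Of the 11 pairs not called 2 passed under an alternative: Solyc02g092820 in root (adjusted p = 0.0227 with the replicate block) and Solyc10g080880 for the difference (adjusted p = 0.0403 without mock leaf library 1). In leaf 5 transport members rose with each tissue fitted alone or after quantile normalization. Solyc11g013310 in leaf lost its call in 18 of 22 alternatives, Solyc12g005940 in root in 12 of 22, Solyc04g076850 and Solyc09g014380 for the difference in 10 and 9 of 21, and Solyc09g010430 in 8 of 16. Without 2,4-D library 1 the calls of Solyc04g076850 in root and Solyc08g076335 for the difference ended (highest adjusted p over the alternatives 0.237 and 0.0702), and without 2,4-D library 2 that of Solyc03g120500 (0.0727).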

Other observations

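The tests on green tissue and on neighbouring loci were chosen after their results had been seen, and those on splits of the leaf libraries, carry-over and counting noise before.

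All 15 light-harvesting and Rubisco small-subunit loci had lower means under picloram in leaf, with a median log2 fold change of -0.99, and 4 were called. This number was 13 with each tissue fitted alone and 9 with 5 added before the logarithm. Without 1 leaf library it was 0 to 5, with 0 without mock library 2 or picloram library 1, and without 1 root library it was 6 or 7. Among the 4 Solyc02g070950 fell by 1.65 ± 0.38 (SE, adjusted p = 0.0184) and Solyc02g071000 by 1.23 ± 0.29 (SE, adjusted p = 0.0205). The list passed camera (adjusted p = 1.37e-05) but not with an estimated correlation (adjusted p = 0.178). The evening-phased clock list was also lower in leaf (adjusted p = 0.00229, and adjusted p = 0.0535 with an estimated correlation), and the list of both phases, whose members go both ways, was not called in leaf (adjusted p = 0.246). In root that combined list was higher (adjusted p = 0.0453, and adjusted p = 0.112 with an estimated correlation).

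Root libraries numbered 2 held more transcript of leaf-abundant loci than those numbered 1. Of 163 such loci 74 were higher in both libraries numbered 2 and 4 in both numbered 1. RNA or reads carried over from the leaf libraries could give this. The median excess was 0.416% of the leaf level over 151 loci outside the photosynthesis list and 0.484% over 12 loci within it. The loci had been chosen for low root means, which limits the excess inside and outside the list and can bring both closer. Green tissue taken with the root tips predicts the same values as carry-over, so both cannot be told apart. Counting noise was to be excluded if over 9 in 10 loci were higher in the same pair. The share was 45.4%, so that strict bound was not met, although 74 against 4 is far from the equal numbers written for noise.

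The 6 leaf libraries can be divided 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 1463 loci and was the 1 split with as many, the highest other calling 1. For gene lists the real split called 2, and 4 splits, the real one included, called at least as many, the highest other calling 4. The Aux/IAA list itself passed camera in 7 of the 9 other splits, with an adjusted p of 0.00278 at the lowest against 1.5e-09 in the real split. Each of the 9 other splits mixes mock and picloram libraries unequally. Part of the treatment difference thus stays between the sides, and the rest widens the spread within them. These splits are therefore no null, and no conclusion is drawn from them for locus calls or lists.

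Called loci next to each other in identifier order changed in the same direction more often than shuffled calls. In root 36 such pairs occurred against a mean of 16.7, and in leaf 112 against 74.2 (one-sided permutation p = 1e-04 for each, the smallest that 10000 shuffles can give). Pairs of opposite direction numbered 7 against 9.42 and 62 against 74.0. Neighbouring loci may respond together, as with tandem copies, and 0 of the 36 and 112 pairs had equal values, but reads divided between similar copies were not examined.

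55 loci stood at 0 in 1 library and at 50 or more in another of the same group. The Aux/IAA locus Solyc09g065850 is among them, with 0.82 and 0 in mock root, 47.6 and 42.1 on 2,4-D, 0, 303 and 0.47 in mock leaf, and 37.0, 35.1 and 0 under picloram. Of 16149 loci summing to at least 50, 8 had values equal to those of another locus in all 10 libraries.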
